A study of Mus musculus with 24 samples.

How the data were processed

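The data are RNA sequencing libraries of mouse embryos (B6D2F1) made from pools of 10 embryos, collected at the late 2-cell stage (L2C) and the morula stage after injection of Cas9 protein with 3 guide RNAs against Ttf1 or Zfp622, with wild-type embryos as controls. There were 24 libraries in 6 groups of 4. Values are count values of read pairs per gene, as deposited and per the file headers: reads of 150 bases from both ends were aligned with HISAT2 2.2.1, per the labels' protocols, and assigned to exons with featureCounts 2.0.1 with Ensembl release 99 annotation on GRCm38, per the file headers, without a strand option and without counting reads that map to several places. The labels also name the build mm10. Gene symbols were matched for 55144 of 55471 gene identifiers, and 54900 genes had the same coordinates in GENCODE M21.

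Groups were taken from the sample titles. The genotype labels of the Zfp622 libraries count upward, so that 7 name another gene, and the strain labels count upward in the same way; these were not used. Sequencing lane was read from alignment file names in the file headers: all Ttf1 knockout libraries carry lane 1, and all wild-type and Zfp622 knockout libraries lane 2. Wild-type L2C library 4 and wild-type morula libraries 3 and 4 carry a second index number in those names. Replicate numbers did not pair the libraries of different groups, since the correlation between libraries of the same number ran from -0.253 to 0.143 after group means were removed. Total counts ran from 10538723 to 17807596 per library. P-values measure the spread between libraries, each a separate pool of embryos per the labels.

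Each knockout was compared with wild type and with the other knockout within a stage (12 libraries), and wild-type morula with wild-type L2C and each knockout effect between stages (interaction) were compared with all 24 libraries. Genes were kept by filterByExpr of edgeR 4.0.16 with the groups, scaled by TMM, fitted with robust quasi-likelihood models (estimateDisp, glmQLFit, glmQLFTest) in R 4.3.3 and called at a Benjamini-Hochberg adjusted p of at most 0.05 without a fold threshold. The prior count for log2 CPM was 2. The 27 fixed gene lists were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01 and adjusted over the lists of a comparison; "adjusted over the list alone" repeats the gene-level adjustment among the list's members. Lists had at least 3 tested members. They were cytosolic ribosomal proteins, RNA polymerase I transcription, assembly of the large and of the small ribosomal subunit, small nucleolar RNA host genes, translation factors, p53 targets, BCL2 family and caspases, integrated stress response, unfolded protein response of the endoplasmic reticulum, heat shock and chaperones, interferon response, mitosis and cell cycle, proteasome, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, sterol biosynthesis, 2-cell stage transcripts, maternal oocyte transcripts, pluripotency and inner cell mass, trophectoderm, primitive endoderm, cell junctions and compaction, and markers of cumulus and granulosa cells, of sperm and spermatids and of blood cells.

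Groups, comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names both targeted genes, then for each knockout against wild type the 8 largest rises and 8 largest falls past the threshold whose libraries do not overlap and whose higher group has at least 5 CPM (4 and 4 in the other comparisons), leaving out predicted genes, Rik clones, pseudogenes and genes without a symbol. It adds up to 4 members with the smallest p of each list called by camera or with at least 3 members past the threshold, 4 p53 effectors and 6 lineage genes. Genes within 500 kb of a target were tested as its neighbours.

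Alternatives were DESeq2 1.42.0 on the same genes, DESeq2 size factors, total counts only, no filter, no robust fit, replicate number as a block, an absolute log2 fold change of at least 1, each library left out, omission of wild-type libraries with a second index number, fits on the 8 libraries of the groups compared or on all 24, camera with an estimated correlation and fry. Counts thinned to the smallest total and an axis of development from split wild-type libraries were added after results were seen. Overlap of the knockouts was set against simulated unchanged groups and against splits of the wild-type libraries. Development was described by the correlation across genes of each knockout effect with the change between stages in the other knockout, and per library by projection on that axis. Differences of single values between 4 and 4 libraries were tested by exact permutation.

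The procedure was tested on simulated data drawn from the wild-type means of each stage, with known changes put into the Ttf1 knockout libraries. At L2C, over 16309 simulated genes, edgeR recovered 28.4%, 50.6% and 89.3% of genes changed 1.5-fold, 2-fold and 4-fold with 3.6% false calls (DESeq2 6.9%). At morula, over 13837 genes, it recovered 42%, 70.2% and 85.1% with 4.3% false calls (DESeq2 14.1%). Camera called the raised list at each stage (adjusted p = 3.92e-29 and 2.57e-39) and 0 of 20 unchanged lists. Genes were simulated independently and lists drawn at random. The simulation therefore cannot show how often camera calls lists whose genes are correlated.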

Results

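Messenger RNA was counted in 24 libraries from mouse preimplantation embryos of the hybrid strain B6D2F1, with 10 embryos pooled per library. Zygotes had received Cas9 protein and 3 guide RNAs against Ttf1 or against Zfp622, and wild-type embryos served as controls. Each of the 3 genotypes was collected at the late 2-cell stage (L2C) and at the morula stage, with 4 libraries in each of the 6 groups. Total counts per library at L2C ran from 10538723 to 12686381 in wild type, from 10632541 to 11893566 in the Ttf1 knockout and from 12135924 to 13528954 in the Zfp622 knockout. At morula they ran from 14363767 to 17807596, from 14420604 to 15479299 and from 12690369 to 14448490. All levels below are CPM, the counts scaled to library size within a stage unless stated otherwise, errors are SD over 4 libraries, and tests are edgeR with adjusted p. The titles of the wild-type libraries carry the letters NC, which the labels do not explain. The labels do not state whether wild-type zygotes were injected. All 8 Ttf1 knockout libraries carry another lane number than the wild-type and Zfp622 knockout libraries. No fit can therefore separate lane from the Ttf1 contrasts within a stage. A lane effect equal at both stages would cancel in the Ttf1 interaction, but one that differs between stages would not.

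Both targeted transcripts were lower in every library of their own knockout. Ttf1, which encodes the transcription termination factor of RNA polymerase I, lies on chromosome 2 of build GRCm38 from 29060262 to 29087656 on the plus strand (ENSMUSG00000026803). Its level at L2C was 90.6 ± 5.25 CPM (SD, n = 4) in wild type and 33.2 ± 4.67 in the Ttf1 knockout, a log2 fold change of -1.45 (SE 0.11) with adjusted p = 3.21e-07. At morula it was 43.1 ± 1.5 in wild type and 25.4 ± 1.46 in the Ttf1 knockout (log2 fold change -0.76, adjusted p = 3.47e-05). Zfp622, whose yeast homologue acts in maturation of the large ribosomal subunit, lies on chromosome 15 from 25984366 to 25998481 on the plus strand (ENSMUSG00000052253). Its level fell from 197.8 ± 9.46 to 73.9 ± 22.8 CPM at L2C (log2 fold change -1.42, adjusted p = 0.00243) and from 52.1 ± 4.84 to 15.1 ± 6.16 at morula (log2 fold change -1.78, adjusted p = 0.00105). Neither gene passed the test in the other knockout: Ttf1 stood at 90 ± 4.81 and 48.3 ± 6.94 CPM in Zfp622 knockout L2C and morula, and Zfp622 at 184.5 ± 21.7 and 45.3 ± 9.27 in the Ttf1 knockout. The fall of Ttf1 was smaller at morula than at L2C (interaction 0.67 on the log2 scale, adjusted p = 0.0016), while the fall of Zfp622 did not differ past the threshold (adjusted p = 0.524). Transcript remaining after Cas9 cutting says nothing of protein, since small insertions or deletions can leave a transcript in place.

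**Figure D1:**
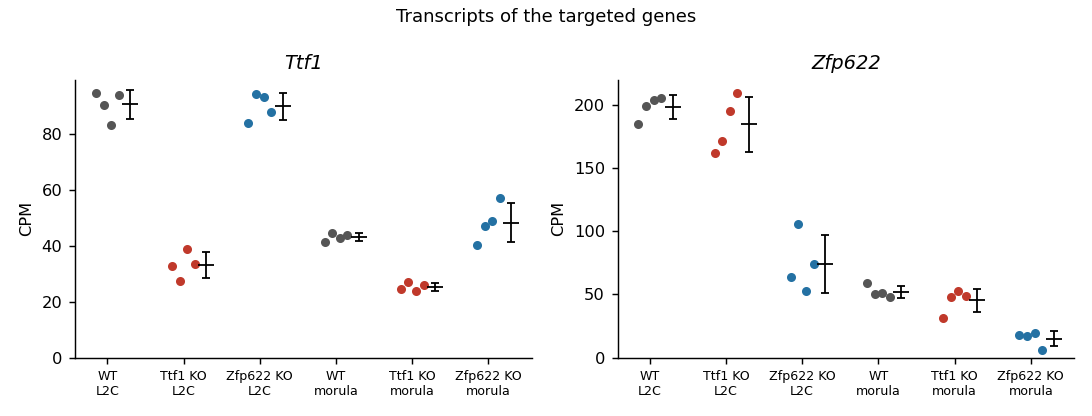
CPM of Ttf1 and Zfp622 in each of the 24 libraries, one point per library, with the group mean and SD (n = 4). Ttf1 was 33.2 against 90.6 CPM in its own knockout at L2C, and Zfp622 was 73.9 against 197.8 CPM in its own.

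Genes within 500 kb of the targets moved in both directions. At L2C Cfap77, a neighbour of Ttf1, passed in the Ttf1 knockout only when adjusted over the neighbours alone (log2 fold change -1.03, adjusted p = 0.00949). At morula 4 of 10 neighbours of Ttf1 passed, 40% against 39.2% of all genes tested: Gtf3c5, Ddx31 and Cfap77 were lower (-0.32, -0.28 and -0.69) and Ak8, an adenylate kinase gene, was higher (1.64, adjusted p = 1.88e-05). Near Zfp622 the only gene tested at L2C, Myo10, did not pass (0.04, adjusted p = 0.982), and at morula Gm4824 was lower (-1.02, adjusted p = 0.00945).

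The question at L2C was what loss of each factor changed soon after the embryo's own genome becomes active. In the Ttf1 knockout, transcripts of cytosolic ribosomal proteins were lower: 15 of 80 members passed the test, all lower, and 34 were lower and 1 higher when adjusted over the list alone. Rps21 fell from 203 ± 25.8 to 134 ± 9.68 CPM and Rpl35 from 143 ± 21.6 to 90.1 ± 8.71 (adjusted p = 0.00348 for both), and Rps24 fell from 515 ± 54.8 to 372 ± 29.4. The list's median log2 fold change was -0.19 (camera adjusted p = 2.39e-09; adjusted p = 0.783 with an estimated correlation). Rps21 and Rpl35 both lie on chromosome 2 distal to Ttf1. So do 22 of the 129 autosomal genes called lower in this comparison, 17.1% against 6.31% of genes tested. The falls named here and in the next paragraph were not separated from the lower median of that arm (-0.106). Among 28 members of the RNA polymerase I machinery Taf1d, a subunit of its promoter selectivity factor, was the 1 that passed, at 418 against 560 CPM (camera adjusted p = 0.0268; adjusted p = 0.783 with an estimated correlation). Of 22 host genes of small nucleolar RNAs, Zfas1 and Taf1d were lower, Zfas1 at 31.6 ± 5.42 against 53.4 ± 7.26 CPM (camera adjusted p = 0.00143; adjusted p = 0.619 with an estimated correlation). Assembly factors went both ways: Brix1, Ebna1bp2 and Znhit6 of the large subunit were lower, as were Esf1 and Utp11 of the small subunit, while Tbl3 and Imp4 of the small subunit were higher (0.46 and 0.32). Those 2 lists were not called by camera (adjusted p = 0.209 and 0.998).

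Few transcripts inherited from the oocyte or made at the 2-cell stage passed the test in Ttf1 knockout L2C embryos. H1foo, the oocyte linker histone, fell from 64.8 ± 10.7 to 36.5 ± 2.23 CPM (adjusted p = 0.00348), and Bcl2l10, an anti-apoptotic oocyte gene, fell by 0.62 on the log2 scale. They were the 2 of 56 maternal oocyte transcripts past the threshold (3 lower adjusted over the list alone; median -0.15; camera adjusted p = 0.00512; adjusted p = 0.817 with an estimated correlation). Of 48 transcripts of the 2-cell stage, the homeobox gene Obox2 was lower at 31.7 against 46.4 CPM, the list's median was -0.38, and camera gave adjusted p = 3.43e-08 (adjusted p = 0.783 with an estimated correlation). Translation factors split, with Eif3f higher at 80.7 ± 4.14 against 54.2 ± 3.9 CPM and Eif2s2 and Eif5b lower (-0.52 and -0.37). The largest rise by the naming rule was Xist, the RNA that silences an X chromosome, at 14.2 ± 7.1 against 3.92 ± 1.76 CPM (log2 fold change 1.87, adjusted p = 0.0311). Other rises were Ric8b (1.65), Hsd17b10 (1.26), Tmc6 (1.15), Pycr1 (1.11), G6pc3 (1.00), Tfcp2l1 (0.99) and the mitochondrial proline tRNA mt-Tp, at 25 ± 4.51 against 12.8 ± 1.38 CPM (0.96, adjusted p = 0.00348). Other falls were Sp3os, a noncoding RNA beside Sp3, below 191 ± 28.6 CPM in wild type (-0.89, SE 0.10, adjusted p = 0.00028), Klf10 (-0.90), Ccdc173 (-0.87), Snora57 (-0.83), Glrx (-0.82) and Pfdn4 (-0.78). The p53 effectors did not pass: Cdkn1a, which arrests the cell cycle, stood at 81.1 ± 25.3 against 73.9 ± 11.7 CPM (adjusted p = 0.827), Mdm2, the ligase that degrades p53, had adjusted p = 0.888, and 0 of 42 p53 targets passed in edgeR (6 higher and 4 lower at an unadjusted p under 0.05; 1 and 1 by DESeq2).

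In total 258 of 16770 genes passed in edgeR at L2C after Ttf1 targeting, 124 higher and 134 lower, with 23 changed at least 2-fold and 2676 at an unadjusted p under 0.05. The libraries of the groups did not overlap for 9.94% of genes, where chance gives 2.86%. The count rests on single libraries: it was 60, 114 and 66 without wild-type L2C library 2, 3 or 4, and 99, 127 and 77 without Ttf1 knockout L2C library 2, 3 or 4, while DESeq2 gave 761 and a replicate block 174.

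The Zfp622 knockout changed few transcripts at L2C. Besides Zfp622 itself, Zfp948, a KRAB zinc finger gene, rose from 88.2 ± 4.08 to 142 ± 8.22 CPM (log2 fold change 0.69, adjusted p = 0.000558), and it was also at 165 ± 7.54 in the Ttf1 knockout. H1foo fell to 38.2 ± 4.68 CPM (-0.76, adjusted p = 0.0477), a call lost in 12 of 19 alternative settings. The 48 transcripts of the 2-cell stage had a median log2 fold change of -0.34 with 0 members past the threshold in edgeR, 7 lower at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 2.22e-10; adjusted p = 0.981 with an estimated correlation). Ccng1, a p53-induced cyclin, was at 36.7 ± 8.28 against 22.2 ± 2.94 CPM without passing (adjusted p = 0.419), and 0 of 42 p53 targets passed in edgeR, 2 when adjusted over the list alone (4 higher and 3 lower at an unadjusted p under 0.05; 1 by DESeq2). Of the 80 ribosomal protein transcripts 0 passed in edgeR, 4 were higher at an unadjusted p under 0.05 and 0 passed by DESeq2 (median 0.02, camera adjusted p = 0.722). The 3 genes that passed among 16770 compare with 1079 at an unadjusted p under 0.05 and 21 by DESeq2. The replicate block gave 2, and the count was 7 without Zfp622 knockout L2C library 2.

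By the morula stage p53-induced genes were strongly raised after Ttf1 targeting. Cdkn1a rose from 51.5 ± 9.34 to 319 ± 69.5 CPM (log2 fold change 2.63, SE 0.21, adjusted p = 7.86e-06). Mdm2 rose from 61.3 ± 5.96 to 201 ± 28.3, Ccng1 from 72.4 ± 9.41 to 243 ± 50.9, and Trp53inp1, a proapoptotic cofactor of p53, from 47.8 ± 7.18 to 197 ± 27.4 CPM. Of 48 p53 targets, 37 were higher, 2 lower and 9 did not pass, with a median of 1.04 (37 higher and 3 lower adjusted over the list alone; camera adjusted p = 1.9e-12; adjusted p = 0.322 with an estimated correlation). The death receptor gene Eda2r (2.35), the RNA-binding protein gene Zmat3 (2.00), the stress gene Sesn2 (1.57) and the nuclease gene Aen (0.81) were among them, and the repair gene Xpc and the fructose bisphosphatase gene Tigar were lower (-0.72 and -0.42). The BH3-only killers Pmaip1 (12.1 ± 2.7 to 65 ± 17.3 CPM) and Bbc3 and the apoptosome gene Apaf1 rose, though the 25 members of the BCL2 family and caspases went both ways (8 higher, 4 lower, camera adjusted p = 0.226).

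**Figure D2:**
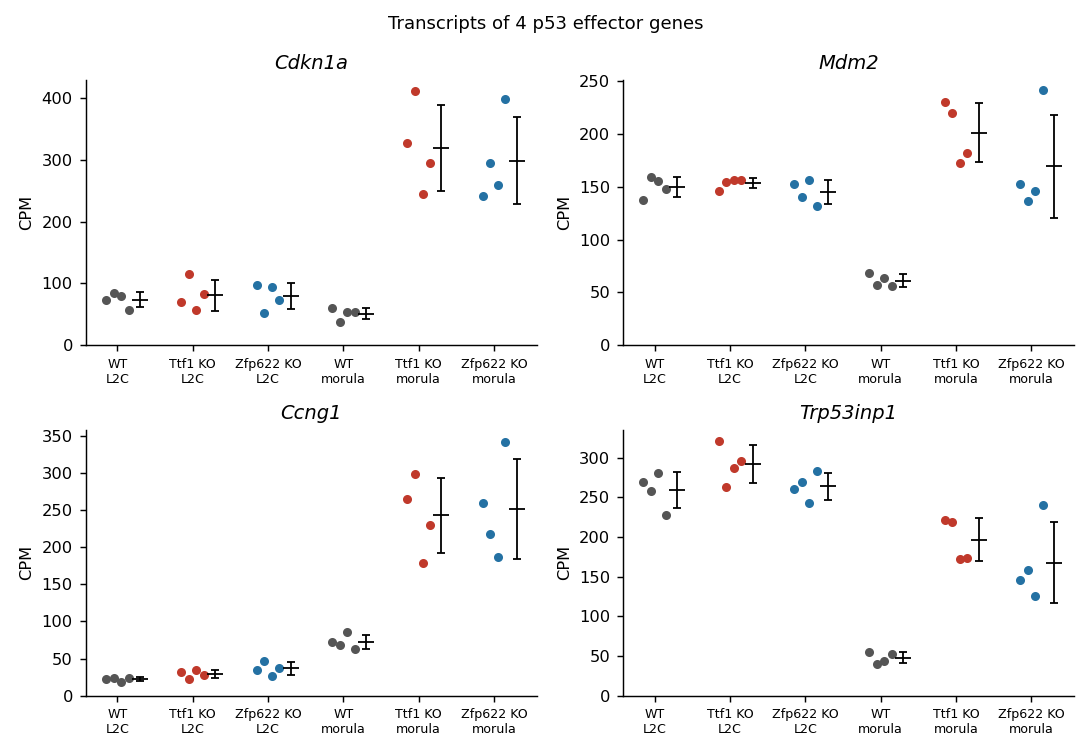
CPM of Cdkn1a, Mdm2, Ccng1 and Trp53inp1 in each library, one point per library, with group means and SD (n = 4). At morula Cdkn1a averaged 51.5 CPM in wild type, 319 in the Ttf1 knockout and 298 in the Zfp622 knockout.

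Transcripts typical of the oocyte and the 2-cell stage were higher in Ttf1 knockout morulae, though at low levels. Of 42 maternal oocyte transcripts 25 were higher and 1 lower (median 1.21; camera adjusted p = 1.08e-07; adjusted p = 0.188 with an estimated correlation). Oog3, an oocyte-specific gene, was at 10.7 ± 1.91 against 1.78 ± 0.272 CPM (adjusted p = 5.69e-07), Omt2b at 10.1 ± 1.57 against 2.42 ± 0.498, and Oosp1 at 6.56 against 1.05, while Khdc3, a member of the subcortical maternal complex, fell from 350 to 217 CPM. Of 43 transcripts of the 2-cell stage 16 were higher and 3 lower, 19 and 3 adjusted over the list alone (median 1.37; camera adjusted p = 0.00265; adjusted p = 0.425 with an estimated correlation). Tdpoz4 stood at 12.9 ± 5.31 against 2.98 ± 0.648 CPM and Arg2, a mitochondrial arginase, at 16.7 ± 3.66 against 6.88 ± 1.1. Mitochondrially encoded transcripts were higher too, with 10 of 15 past the threshold and mt-Nd2 at 2959 ± 375 against 1809 ± 61.3 CPM (camera adjusted p = 0.000534; adjusted p = 0.362 with an estimated correlation). The mitochondrial share of all counts was 3.47% ± 0.253 against 2.36% ± 0.0907. Ribosomal protein transcripts were higher in 47 of 80 cases and lower in 1, 51 and 1 adjusted over the list alone (median 0.25; camera adjusted p = 3.89e-07; adjusted p = 0.427 with an estimated correlation). Rps27l, itself a p53 target, rose from 776 ± 31.1 to 1294 ± 168 CPM, and Rpl3 was the member that fell, from 2185 ± 73.5 to 1564 ± 39.8.

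In the same morulae more members were lower than higher in lists of the cell cycle, proteasome, ribosome assembly, protein folding, translation and junctions. Of 56 mitosis and cell cycle genes 33 were lower and 7 higher (camera adjusted p = 8.44e-06; adjusted p = 0.348 with an estimated correlation). The mitotic kinase gene Aurka fell from 650 ± 27.3 to 384 ± 57.8 CPM and the checkpoint gene Bub1b from 56.7 ± 5.42 to 29.7 ± 4.6. Lower members also prevailed in the proteasome (20 of 37, Psmd2 -0.55; camera adjusted p = 3.62e-05) and in assembly of the small ribosomal subunit (31 of 66, with the acetyltransferase gene Nat10 at -0.99 and Dnttip2 at -0.55; camera adjusted p = 0.000682), with adjusted p = 0.362 with an estimated correlation for each. For assembly of the large subunit 19 of 63 were lower and 6 higher (Heatr3 -0.67, Nop2 -0.73; camera adjusted p = 0.0089; adjusted p = 0.427 with an estimated correlation). The unfolded protein response of the endoplasmic reticulum had 13 of 26 lower (Hspa5, its main chaperone, from 719 ± 237 to 219 ± 119 CPM), heat shock proteins and chaperones 15 of 28 (Hspd1 -1.16, Hspe1 -1.19), and translation factors 12 of 43 (Etf1 -0.44, against Eif1 at 0.50). Camera gave adjusted p = 0.00179, 0.00331 and 0.0305 for these 3 lists, and adjusted p = 0.362 with an estimated correlation for each. Junction and compaction genes had 13 of 44 lower, among them the connexin gene Gja1, from 1818 ± 14.5 to 1213 ± 168 CPM (camera adjusted p = 0.0168; adjusted p = 0.362 with an estimated correlation).

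Among lineage genes of Ttf1 knockout morulae, Nanog, a core pluripotency factor, fell from 620 ± 32.6 to 191 ± 86.8 CPM (log2 fold change -1.70, adjusted p = 0.00282), and Sox2 fell from 2.37 ± 0.694 to 0.764 ± 0.593. Pou5f1 did not pass (106.5 ± 9.53 against 106.2 ± 6.28 CPM, adjusted p = 0.975), nor did Gata6 of the primitive endoderm (adjusted p = 0.269). The trophectoderm regulators Cdx2 (4.55 ± 0.61 against 6.97 ± 0.34 CPM, adjusted p = 0.0108) and Gata3 (44.1 ± 9.77 against 65.9 ± 2.53, adjusted p = 0.00265) were lower. Of 32 pluripotency genes 10 were lower and 4 higher (L1td1 -0.97, Zfp42 -0.81; camera adjusted p = 0.0491), and of 31 trophectoderm genes 13 were lower and 4 higher (Ptges -1.32, Slc2a1 -1.13, against Tspan8 at 1.40; camera adjusted p = 0.0266). Both lists had adjusted p = 0.362 with an estimated correlation. Among the largest rises by the naming rule Hormad1, a meiotic chromosome axis gene, went from 10.9 ± 3.94 to 189 ± 58.9 CPM, and Bbs7 (log2 fold change 5.42), Nectin4 (4.98), Mlana (4.59), the chemokine gene Cxcl10 (4.45), Vmn2r94 (4.36), Zfp750 (4.24) and Cd81 (4.14) came from under 1 CPM. The largest falls were Apoa1, from 25.9 ± 7.04 to 4.93 ± 1.99 CPM, then Glrx (-2.12), C2cd4a (-1.89), the kinase gene Map2k6 (-1.87), Tpra1 (-1.83), Hspa5 (-1.71), Nanog (-1.70) and Nlrp4c (-1.68). Cd81 lost its call only where the wild-type libraries with a second index number were left out.

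Among markers of other cells, those of blood stood apart from wild type in both knockouts at morula. Summed transcripts of 18 blood markers were at 29.4 ± 7.61 CPM in Ttf1 knockout and 33 ± 4.47 in Zfp622 knockout morulae, against 12.9 ± 1.59 in wild type. Most of this was Cd68 (18.2 and 23.7 against 9.6 CPM) and Hba-a1 (6.7 and 5.64 against 1.62), while Ptprc, Tyrobp, Fcer1g, S100a8, S100a9 and Hbb-bs were at or near 0 in every morula group. In the Ttf1 knockout 3 of 4 tested blood markers were higher (Hba-a1 from 1.62 to 6.7 CPM; camera adjusted p = 0.0291; adjusted p = 0.322 with an estimated correlation). The 21 sperm markers summed to 22.4 ± 3.29 and 27.3 ± 2.36 against 19.6 ± 2.3 CPM, and the 33 cumulus and granulosa markers to 39.8 ± 5.2 and 39.1 ± 3.05 against 35.8 ± 4.07. In the Ttf1 knockout 2 of 3 tested sperm markers and 4 of 9 cumulus markers were higher, and camera called neither list (adjusted p = 0.121 and 0.394).

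For the Ttf1 knockout at morula, 5833 of 14865 genes passed in edgeR, 3170 higher and 2663 lower, of which 1516 and 298 changed at least 2-fold. With the replicate block 5532 passed, and without the wild-type libraries that carry a second index number 3553 passed.

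In Zfp622 knockout morulae p53 targets were higher than in wild type as well. Cdkn1a stood at 298 ± 69.7 CPM (log2 fold change 2.54, SE 0.21, adjusted p = 2.61e-05), Mdm2 at 169 ± 48.9, Ccng1 at 251 ± 67.3 and Trp53inp1 at 168 ± 50.7, each above wild type in all 4 libraries. Of 48 p53 targets 37 were higher and 0 lower in edgeR, 38 and 0 adjusted over the list alone, 38 and 2 at an unadjusted p under 0.05, and 37 and 0 by DESeq2 (median 0.99; camera adjusted p = 2.82e-14; adjusted p = 0.222 with an estimated correlation). Eda2r rose from 16.2 ± 2.56 to 67.6 ± 9.43 CPM, and Zmat3 (1.82), Pmaip1 (2.45) and Bbc3 (2.54) rose with it. Maternal oocyte transcripts were higher in 26 of 42 cases and lower in 2 (Oog3 at 11.4 ± 2.26 CPM, Omt2b 1.97, Fbxw24 1.91; camera adjusted p = 3.67e-08; adjusted p = 0.159 with an estimated correlation). Transcripts of the 2-cell stage were higher in 12 of 43 and lower in 3, 16 and 3 adjusted over the list alone (Arg2 1.42, Tdpoz4 1.78; camera adjusted p = 0.00106; adjusted p = 0.349 with an estimated correlation). Of 15 mitochondrially encoded transcripts 9 were higher (mt-Cytb 0.56; camera adjusted p = 0.00176; adjusted p = 0.319 with an estimated correlation), and their share of counts was 3.17% ± 0.406. Ribosomal protein transcripts were higher in 24 of 80 cases with Rpl3 again the 1 that fell (-0.33; camera adjusted p = 0.000575; adjusted p = 0.576 with an estimated correlation).

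**Figure D3:**
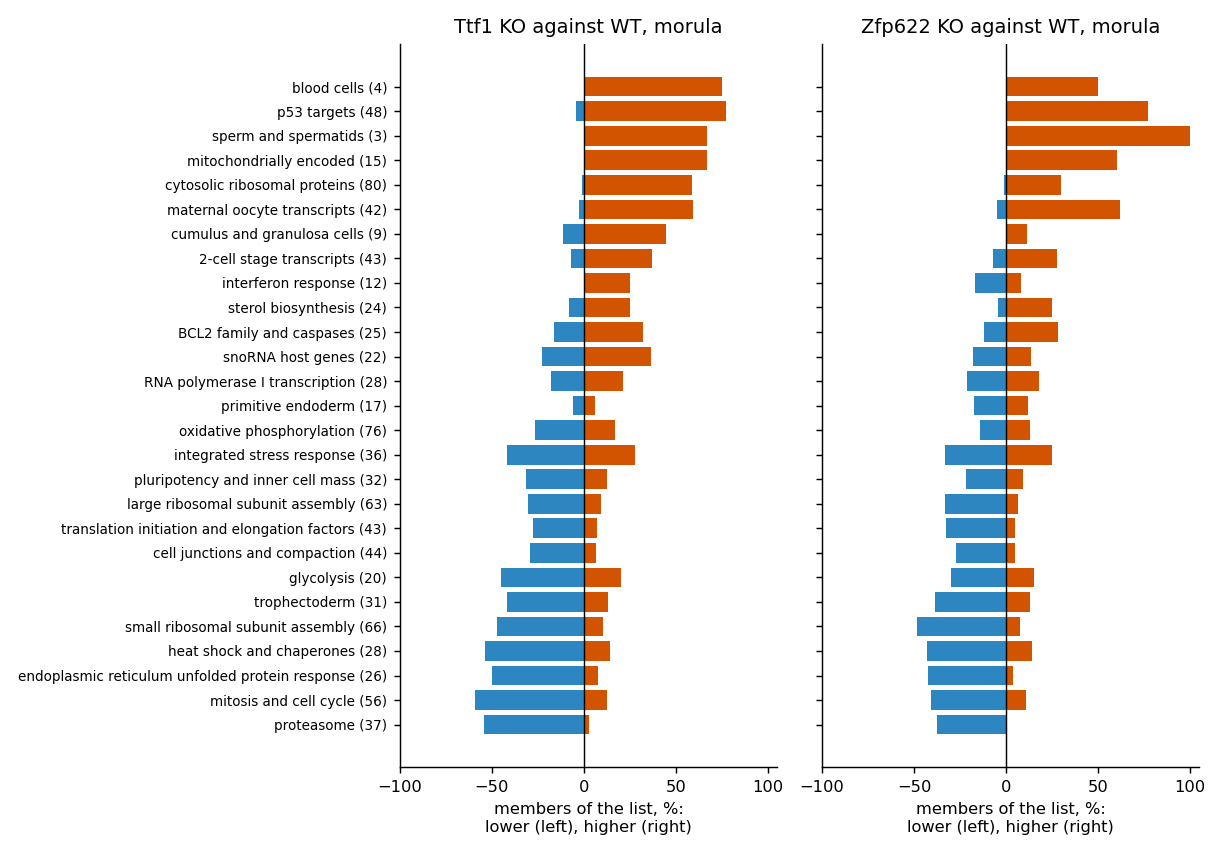
Percentage of members of each fixed gene list called higher (right) and lower (left) than wild type at morula, in each knockout. The median log2 fold changes, which are not drawn, were 1.04 in the Ttf1 knockout and 0.99 in the Zfp622 knockout for p53 targets. For mitosis genes they were -0.33 and -0.24.

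Lowered groups in Zfp622 knockout morulae included both lists of ribosome assembly. Of 66 small subunit factors 32 were lower and 5 higher (Dnttip2 -0.53, Nat10 -0.77; camera adjusted p = 7.4e-06), and of 63 large subunit factors 21 were lower and 4 higher (Heatr3 -0.50, Ddx18 -0.45; camera adjusted p = 0.000648). Mitosis and cell cycle genes had 23 of 56 lower (Aurka -0.54) while Ccnd1, a G1 cyclin, rose from 3.99 ± 1.39 to 15.4 ± 1.21 CPM (camera adjusted p = 0.000212). The proteasome had 14 of 37 lower (Psmd2 -0.47; camera adjusted p = 0.000394), translation factors 14 of 43 lower and 2 higher (Eif3d -0.53; camera adjusted p = 0.00176), and the endoplasmic reticulum response 11 of 26 lower (Derl1 -0.72; camera adjusted p = 0.00399). Junction genes had 12 of 44 lower, with the claudin gene Cldn7 from 294 ± 41.1 to 148 ± 37.6 CPM (camera adjusted p = 0.00479). Trophectoderm genes had 12 of 31 lower, with the endocytic receptor gene Lrp2 from 110 ± 5.77 to 54.1 ± 14.3 CPM (camera adjusted p = 0.0212), and pluripotency genes 7 of 32 lower and 3 higher, with Dppa3 up from 4389 ± 116 to 6333 ± 702 CPM and Zfp42 down (-0.70; camera adjusted p = 0.0301). Each of these 9 lists had adjusted p = 0.319 with an estimated correlation. For chaperones the median (-0.14) and the mean (0.14) differed in sign: Hspa1b, a stress-induced Hsp70, rose from 1.33 ± 0.608 to 8.65 ± 1.54 CPM while 12 of 28 members fell (camera adjusted p = 0.0204; adjusted p = 0.34 with an estimated correlation).

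Nanog was at 332 CPM (195.6 to 456.8 over the libraries) in Zfp622 knockout morulae and did not pass (log2 fold change -0.90, adjusted p = 0.062). Sox2 (-1.65), Gata3 (-0.57) and Cdx2 (-0.50, adjusted p = 0.0434) were lower, the last with a call lost in 13 of 19 alternative settings, and Pou5f1 and Gata6 did not pass (adjusted p = 0.862 and 0.648). The largest rises were Bbs7 (5.74), Cxcl10 (4.92, at 12.3 ± 3.13 CPM), Cd81 (4.71), Mlana (4.64), Nectin4 (4.50), the adhesion gene Mcam (4.35), the homeobox gene Nkx2-9 (4.11) and Zfp750 (3.99). The largest falls after Zfp622 were Apoa1 (5.61 ± 3.63 CPM), Map2k6 (-2.00), Add3 (-1.77), Xlr3b (-1.73), Mipol1 (-1.67), Uchl1 (-1.64) and Mocos (-1.60). Sperm markers passed in 3 of 3 cases, with Prm2, a protamine gene, at 0.774 against 0.0171 CPM (camera adjusted p = 0.0264; adjusted p = 0.252 with an estimated correlation). Blood markers passed in 2 of 4, 4 adjusted over the list alone (Cd68 from 9.6 to 23.7 CPM; camera adjusted p = 0.0165; adjusted p = 0.222 with an estimated correlation). In all 4321 of 14865 genes passed, 2313 higher and 2008 lower, of which 1103 and 175 changed at least 2-fold. The replicate block gave 4037, and without the wild-type libraries with a second index number the count was 2043.

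At morula the knockouts resembled each other closely. Of the genes past the threshold, 3619 moved the same way in both knockouts, 1966 up and 1653 down, and 3 moved oppositely; this is 83.8% of the shorter list. Both contrasts share the wild-type libraries, which raises the overlap. Independent lists give 853. Splitting the wild-type libraries 2 and 2 between the knockouts left 1886 on average (1831 to 1968 over 6 splits), where independent lists give 331.3. With fewer wild-type libraries per contrast the lists were shorter too, 4076 and 2606 genes on average against 5833 and 4321. The overlap was then 72.4% of the shorter list, so the fall from 3619 mixes the loss of sharing with shorter lists. Unchanged simulated groups gave 0 in each of 10 runs. Only 0.3 and 0.2 genes were called in them on average, so that 0 does not measure what shared libraries add to long lists. Across genes, which are not independent replicates, the log2 fold changes had r = 0.901 and a covariance of 0.485. Simulated unchanged groups gave r = 0.490 with a covariance of 0.0495. Split wild-type libraries gave r = 0.720 with a covariance of 0.538, over a larger set of about 16030 genes. At L2C 2 genes were shared, Zfp948 and H1foo, with r = 0.616 and a covariance of 0.0765 against 0.508 and 0.0474 for simulated unchanged groups, and 0.183 and 0.0437 for split wild-type libraries.

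**Figure D4:**
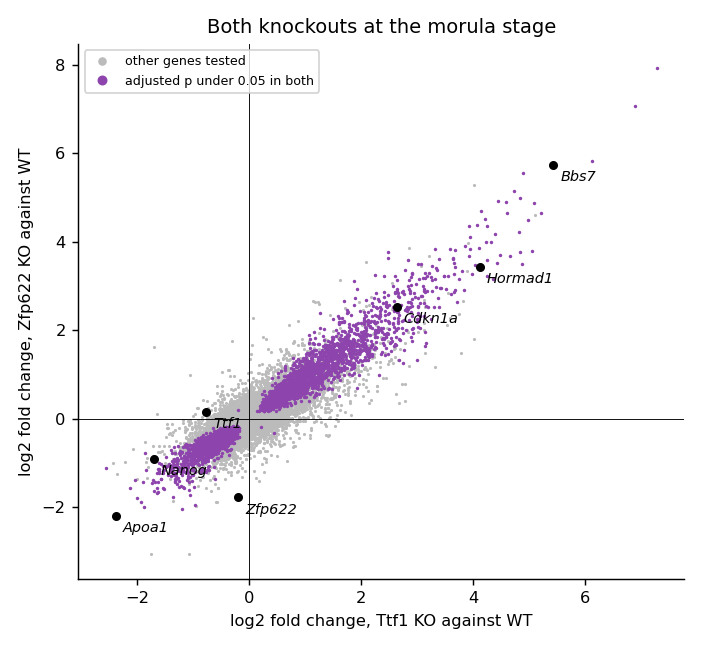
Log2 fold change against wild type at morula in the Zfp622 knockout against that in the Ttf1 knockout, one point per gene tested. Across genes r was 0.901 with a covariance of 0.485, against 0.490 and 0.0495 in simulated unchanged groups that share their wild-type libraries.

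The direct comparison asked which transcripts separate the knockouts from each other. At morula the B-type cyclin gene Ccnb3 was at 5.16 ± 0.569 CPM in the Ttf1 knockout against 1.86 ± 0.391 in the Zfp622 knockout, the septin gene Sept10 at 18.3 ± 3.83 against 7.83 ± 1.91, and Dynap and Ltbp4 were higher as well (1.09 and 0.99). Besides Ttf1 itself (-0.93), Clp1, an RNA 5' kinase gene, was lower at 82 ± 12.7 against 132 ± 15 CPM, with Ivd (-0.83) and AI413582 (-0.67). Of the 15 genes called lower 6, among them Clp1 and Ivd, lie on chromosome 2 distal to Ttf1, 40% against 6.66% of genes tested, and at L2C 2 of 3 do. In all 34 of 14865 genes passed, 19 higher and 15 lower, with 1959 at an unadjusted p under 0.05. Of 48 p53 targets 0 passed in edgeR, 3 were higher and 3 lower at an unadjusted p under 0.05, 1 and 1 passed by DESeq2, and the list was not called (camera adjusted p = 0.339). Camera called ribosomal proteins higher (adjusted p = 0.000264), and chaperones and mitosis genes lower (0.0165 and 0.00707), with adjusted p = 0.882 with an estimated correlation for each. The count of 34 was 15 with the replicate block, 323 by DESeq2, 150 without Ttf1 knockout library 1, 3, 2 and 15 without libraries 2, 3 and 4, and 4, 14, 7 and 119 without Zfp622 knockout libraries 1 to 4. At L2C 6 of 16770 genes passed (1362 unadjusted, 73 by DESeq2, 3 with the replicate block): the named ones were Zfp622 (1.32), Ttf1 (-1.44), Sp3os (-0.60) and Rps21, at 134 ± 9.68 against 194 ± 13.1 CPM (-0.53, adjusted p = 0.0355). The count was 2 without Ttf1 knockout L2C library 1, 2 or 4 and 1 without Zfp622 knockout L2C library 4. Adjusted over the list alone, 42 of 80 ribosomal protein transcripts were lower in the Ttf1 knockout than in the Zfp622 knockout at L2C (median -0.22; camera adjusted p = 3.4e-19; adjusted p = 0.524 with an estimated correlation).

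Normal development from L2C to morula set the frame for these differences, here with all 24 libraries scaled together. Vnn1, a pantetheinase gene, went from 0.113 to 496 CPM, and Serpinb9b from 0.0179 to 80.7. Serpinb6c (39.6 CPM at morula) and Apoa1 (31.7) had a count of 0 in all 4 wild-type L2C libraries. The oocyte genes Tcl1b1 and Tcl1b4 went from 1340 to 0.464 and from 377 to 0.121 CPM, and Hnmt (24.8) and the nuclear receptor gene Esrrg (22.1) had a count of 0 in the wild-type morula libraries. Ribosomal proteins were higher at morula in 78 of 80 cases, oxidative phosphorylation in 74 of 76 and the proteasome in 34 of 37, whereas maternal oocyte transcripts were lower in 55 of 56 and transcripts of the 2-cell stage in 43 of 48. Camera gave adjusted p = 6.59e-24, 2.59e-19, 1.75e-12, 4.61e-16 and 2.32e-06 for these lists, and adjusted p = 0.121, 0.121, 0.121, 0.0255 and 0.277 with an estimated correlation. Trophectoderm genes were higher in 26 of 32 cases (camera adjusted p = 5.93e-07; adjusted p = 0.00804 with an estimated correlation). Of 18864 genes 15842 passed, 7141 higher and 8701 lower (5595 and 10420 with total counts alone), 13108 of them at least 2-fold; the replicate block gave 15779. Scaling mattered here: the median log2 fold change of all genes was -0.30 with TMM and -0.87 with total counts alone, which also turned the sign of 456 called genes.

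Whether the knockout effects differed between the stages was tested by interaction, again with all 24 libraries. In the Ttf1 knockout 3992 of 18864 genes passed, 2361 in the upward and 1631 in the downward direction. Bbs7 (5.78) and Nectin4 (5.71) led the upward side; Mlana averaged 7.65 CPM in Ttf1 knockout morulae against 0.296 in wild type with 0 counts in the Ttf1 knockout at L2C, and Hs6st2 had a count of 0 in wild-type morulae. Magea8 (-3.47), the polo-like kinase gene Plk5 (-3.40), Gsdma3 (-3.23) and Magea2 (-3.12) led the downward side. Among 49 p53 targets 27 were more raised at morula than at L2C (camera adjusted p = 3.01e-12; adjusted p = 0.088 with an estimated correlation). For the Zfp622 knockout 2010 genes passed, 1216 upward and 794 downward, with Nectin4 (5.75), Bbs7 (5.69) and Mlana (5.66) on the upward side and Msrb2 (-3.49) and Itga1 (-2.92) on the downward side. Fkbp14 had a count of 0 in wild-type morulae, and Serpinb6c and Dusp3 in wild-type L2C embryos, so their folds are left out. Of the p53 targets 24 were more raised at morula (camera adjusted p = 2.31e-15; adjusted p = 0.0343 with an estimated correlation). The replicate block gave 3788 and 1829 genes. Without the wild-type libraries with a second index number the counts were 2132 and 646, and without Zfp622 knockout morula library 4 the Zfp622 count was 1339.

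The position of each knockout along normal development was measured across genes, against the change between stages in the other knockout. Ttf1 knockout morulae lay on the L2C side of wild type (r = -0.188, covariance -0.157 over 18864 genes), and so did Zfp622 knockout morulae (r = -0.118, covariance -0.0842). The size depends on the axis: with the change in wild type, its libraries split so that none was shared, r was -0.351 and -0.316. The axis from the other knockout, also used per library, holds that knockout's own morula effect. The effects of the knockouts at morula had a positive covariance with split wild-type libraries (0.538), which draws r on that axis upward. That covariance is of edgeR fold changes over about 16030 genes, so only its sign, not its size, bears on the covariances above. Per library the shift was -5.31% ± 1.54 of the axis for Ttf1 and -3% ± 1.12 for Zfp622, with an exact two-sided permutation p = 0.0286 for each, the smallest 4 against 4 libraries allow, and 0.0572 after adjustment over the 4 tests. At L2C the shifts were 1.84% ± 2.2 and 1.11% ± 3.99 (exact permutation p = 0.343 and 0.657). Genes are not independent replicates, so the correlations carry no p.

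Genes distal to the target on the same chromosome had lower medians than other autosomes at morula, by more in their own knockout than in the other. On chromosome 2 the 951 genes distal to Ttf1 had a median log2 fold change of -0.165 in Ttf1 knockout morulae, against 0.0461 for other autosomes, and 0 of 2443 runs of as many neighbouring genes elsewhere were as low. These runs overlap one another, so the counts and shares of runs given here are not those of independent comparisons. The 170 genes proximal to Ttf1 had a median of -0.0693. In Zfp622 knockout morulae the same distal genes had a median of -0.0219 against 0.03 for other autosomes, with 3.48% of runs lower. At L2C the median of 1015 distal genes was -0.106 in the Ttf1 knockout, and 22 of the 129 autosomal genes called lower lay there, 17.1% against 6.31% of genes tested. On chromosome 15 the 476 genes distal to Zfp622 had a median of -0.0612 in Zfp622 knockout morulae, against 0.0294 for other autosomes, with 0.451% of runs lower. In Ttf1 knockout morulae they had -0.00768 against 0.0324, with 20.8% of runs lower, and per library -0.0403 ± 0.0195 (exact permutation p = 0.0571). At L2C the median of 547 distal genes was -0.0444 in the Zfp622 knockout, with 0 of 2985 runs lower. Per morula library the distal genes were below the rest by -0.216 ± 0.0787 in the Ttf1 knockout and -0.0941 ± 0.0335 in the Zfp622 knockout, each with exact two-sided permutation p = 0.0286 and 0.114 after adjustment over 8 tests. Per L2C library the differences were -0.109 ± 0.109 and -0.0415 ± 0.0597 (exact permutation p = 0.143 and 0.343), and library 3 of the Ttf1 knockout (0.0257) and library 4 of the Zfp622 knockout (0.0282) lay above all wild-type libraries.

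**Figure D5:**
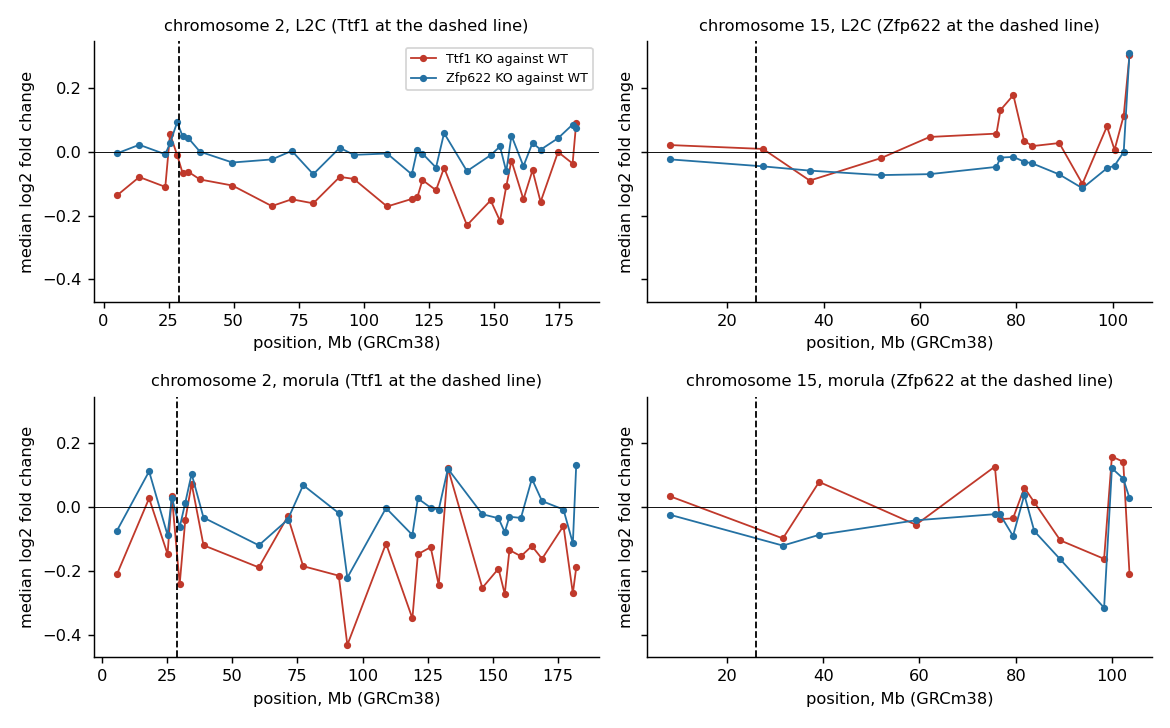
Median log2 fold change against wild type along the chromosomes of the targets, in bins of neighbouring genes, with each target marked. Distal to Ttf1 the median over all genes was -0.165 at morula in its own knockout and -0.0219 in the other.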

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

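No test in this part was chosen after the result was seen. With 4 libraries per group, a Dixon test of single values passes by chance in about 1 in 20 groups: 6 of 114 tests passed, where 5.7 are expected. In Ttf1 knockout morula library 2 the total count (14420604, or 14.42 on the scale of the test) was below that of the others of its group (15.39 to 15.48). The share of protein-coding counts in wild-type morula library 1 was 93.04%, against 93.57 to 93.67%. Mdm2 stood at 146 CPM in Ttf1 knockout L2C library 1 (others 154.8 to 156.5) and at 241.8 CPM in Zfp622 knockout morula library 4 (others 136.3 to 152.6). Cdx2 stood at 0.3493 CPM in Ttf1 knockout L2C library 4, and the others of the group were at 0. Gata3 stood at 4.204 CPM in wild-type L2C library 1 (others 6.467 to 6.674).

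Knockout effects differed between the stages for 3992 genes in the Ttf1 knockout and 2010 in the Zfp622 knockout, and the knockouts differed from each other for 6 genes at L2C and 34 at morula.

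Other splits of the same libraries show how often another grouping gives as many genes, where 1 of 35 is the smallest share possible. The real count was far above every other split for Ttf1 against wild type at L2C (258 genes, 1 of 35 splits gave as many, highest other 1). So it was for Ttf1 at morula (5833, 1 of 35, highest other 0) and Zfp622 at morula (4321, 1 of 35, highest other 1). Wild-type morula against L2C was alike (15842, 1 of 35, highest other 0). In the direct comparison at L2C (6, 1 of 35, highest other 1) the genes include both targeted genes. In that at morula (34, 1 of 35, highest other 27) another split came near the real count. Leaving out 1 library moved that count from 2 to 150, so chance cannot be excluded there. For the interactions the share of splits is low, for Ttf1 (3992; 1 of 100, highest other 3730) and for Zfp622 (2010; 2 of 100, highest other 2184). The split with 3730 exchanges wild-type L2C library 1 with Ttf1 knockout L2C library 1, and that with 2184, above the real count, exchanges it with Zfp622 knockout L2C library 4. Chance cannot be excluded for Zfp622 against wild type at L2C (3; 2 of 35): the split that exchanges wild-type L2C library 2 and Zfp622 knockout L2C library 2 called 216 genes, which points to a structure of the samples.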

How the results depend on the processing

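Thinned counts and the wild-type axis of development were chosen after results were seen; the other alternatives were planned. The causes of the shifts below were not tested. No list called by camera turned direction with total counts only, DESeq2 size factors or fry. An estimated correlation lost nearly all calls: 5 of 5 and 16 of 16 for Ttf1 against wild type at L2C and morula. For Zfp622 it lost 1 of 1 and 17 of 17, and for the direct comparisons 1 of 1 and 3 of 3. It lost 11 of 13 calls for the stages, and 13 of 13 and 12 of 14 for the Ttf1 and Zfp622 interactions. Total counts only lost 1 of 5 calls for Ttf1 at L2C and 2 of 13 for the stages, where DESeq2 size factors lost 1 of 13, and fry lost 1 of 13 and 3 of 14 for the Ttf1 and Zfp622 interactions. Fry lost 4 of 5 for Ttf1 at L2C (adjusted p = 0.156 for ribosomal proteins, 0.262 for RNA polymerase I, 0.35 for 2-cell and 0.381 for maternal transcripts), the 1 for Zfp622 at L2C (0.821), the 1 for the direct comparison at L2C (0.0704) and all 3 at morula (0.456 each), and 0 of 16 and 0 of 17 for Ttf1 and Zfp622 against wild type at morula. For Ttf1 against wild type at L2C (258 genes) DESeq2 gave 761 (247 shared), no filter 769, the fold threshold 23, omission of wild-type libraries with a second index number 66, the 8-library fit 482 and the 24-library fit 389; leaving out 1 library gave 60 (without wild-type L2C library 2) to 198, with 114, 66, 99, 127 and 77 without wild-type libraries 3 and 4 and Ttf1 knockout libraries 2, 3 and 4. The replicate block gave 174 there, 5532 and 4037 for Ttf1 and Zfp622 at morula, 2 for Zfp622 at L2C, 15779 for the stages, and 3788 and 1829 for the interactions. For Ttf1 at morula the fold threshold gave 1814 and omission of the second-index libraries 3553, with 4930 to 5773 over single omissions. Zfp622 at L2C gave 21 by DESeq2, 88 without filter, 1 with the fold threshold, 6 with 24 libraries, and 2 to 7 over single omissions (7 without Zfp622 knockout L2C library 2). Zfp622 at morula gave 1278 and 2043 for the fold threshold and the second-index libraries, and 3320 to 4165. The stage comparison gave 15775 to 15925. The Ttf1 interaction gave 2006 and 2132, and 3357 to 4098; the Zfp622 interaction 1032 and 646, and 1339 (without Zfp622 knockout morula library 4) to 2185. The direct comparison at L2C gave 73 by DESeq2, 84 without filter, 3 with the block, 20 with 24 libraries, and 1 to 5 over omissions (2 without Ttf1 knockout library 1, 2 or 4; 1 without Zfp622 knockout library 4). At morula it gave 323 (32 of 34 shared), 368, 15 with the block, 8 with the fold threshold, 9 with 8 libraries, 57 with 24, and 2 to 150 over omissions: 150, 3, 2 and 15 without Ttf1 knockout libraries 1 to 4, and 4, 14, 7 and 119 without Zfp622 knockout libraries 1 to 4. With the fold threshold the overlap was 0 at L2C and 1039 at morula. For position along development r was -0.248 (Ttf1) and -0.178 (Zfp622) over genes of at least 5 CPM, and -0.351 and -0.316 with the wild-type axis. Total counts alone shifted the share of higher calls from 48.1% to 59.5% for Ttf1 at L2C and from 55.9% to 40.7% for the direct comparison at morula.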

Other observations

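Lane tests, the test of a delay between the stages for p53 targets and the test of the L2C share needed were chosen after the result was seen. So were the arm tests in the other knockout, per library and proximal to the target. The lists below were not called by camera at morula, where 39.2% of all genes passed in the Ttf1 knockout and 29.1% in the Zfp622 knockout, so shares near these do not set a list apart. Of 24 sterol synthesis genes 6 were higher and 2 lower in the Ttf1 knockout (Fdft1, squalene synthase, at 393 against 219 CPM) and 6 and 1 in the Zfp622 knockout (Idi1 at 50.6 against 28.8; camera adjusted p = 0.226 and 0.2). The integrated stress response had 10 higher and 15 lower of 36 in the Ttf1 knockout and 9 and 12 in the Zfp622 knockout (camera adjusted p = 0.307 and 0.505), with medians of -0.20 and -0.09 and means of 0.21 and 0.26: Ddit4, an inhibitor of mTORC1 signalling, rose from 3.17 to 10.4 and 11.5 CPM, while the tRNA synthetase gene Sars fell from 144 to 77 and 90.1. Of 76 oxidative phosphorylation genes 13 were higher and 20 lower, and 10 and 11 (Ndufb6 0.90 and 0.78, Atp5a1 -0.50 and -0.50; camera adjusted p = 0.243 and 0.43). Glycolysis had 4 higher and 9 lower of 20, and 3 and 6 (Ldhb 1.60 and 1.37, Pgk1 -0.79 and -0.51; camera adjusted p = 0.149 and 0.512), with a median of -0.10 and a mean of 0.05 in the Zfp622 knockout.

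RNA polymerase I genes had 6 higher and 5 lower of 28 in the Ttf1 knockout and 5 and 6 in the Zfp622 knockout, with Polr1b, its second-largest subunit, from 123 to 74.6 and 82.9 CPM (camera adjusted p = 0.978 and 0.312). Hosts of small nucleolar RNAs had 8 higher and 5 lower of 22, and 3 and 4 (Snhg15 0.80 and 0.73, Snhg11 -1.36 and -1.04; camera adjusted p = 0.506 and 0.941). The BCL2 family and caspases in the Zfp622 knockout had 7 higher and 3 lower of 25, with Casp6 from 193 to 110 CPM (camera adjusted p = 0.16). Primitive endoderm genes had 1 and 1 of 17, and 2 and 3, with Apoe from 12.9 to 47.7 CPM in the Zfp622 knockout (camera adjusted p = 0.585 and 0.147). Interferon response genes had 3 higher of 12, and 1 higher and 2 lower, with Ifi27 from 0.922 to 2.75 and 2.74 CPM and Oasl2 lower in the Zfp622 knockout (-1.20; camera adjusted p = 0.497 and 0.601). Of 9 cumulus markers 1 was higher in the Zfp622 knockout (camera adjusted p = 0.682). At L2C the Y-linked Uty was at 33 ± 0.463 CPM in wild type, 20.3 ± 4.61 in the Ttf1 knockout and 21.4 ± 2.71 in the Zfp622 knockout, where Xist was at 3.92 ± 1.76, 14.2 ± 7.1 and 7.99 ± 2.39; the sex of the pooled embryos is not given.

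The rise of p53 targets at morula was not tied to lane, since the Zfp622 libraries, in the lane of wild type, had a median of 0.99, nor to depth, since at least 97.3% of members called higher stayed so at equal depth. A delay could account for part of it: 39.6% of members, among them Cdkn1a, Mdm2 and Pmaip1, lay above all wild-type libraries of both stages in all 8 knockout libraries, between the limits set for the test. A response to Cas9 cutting or injection stays open, since the labels do not say whether wild-type zygotes were injected, and no value here decides it: 0% of members differed between the knockouts in edgeR (3 higher and 3 lower of 48 at an unadjusted p under 0.05, 1 and 1 by DESeq2), but 34 of 14865 genes did in all, so nearly any list would give this. These explanations and loss of either factor cannot be told apart here.

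Maternal and 2-cell transcripts were higher in morulae at equal depth too (at least 89.5% of calls kept), and in the lane of wild type (median at least 1.04). A general delay is a candidate explanation: the knockout effects correlated with the wild-type change between stages at r = -0.351 and -0.316, past the limit of -0.3. With the change in the other knockout as axis r was -0.188 and -0.118, short of it. That axis holds the other knockout's own morula effect, which covaries positively with the effect tested, so its smaller r cannot decide on a delay. Mixing of L2C embryos or their RNA into the pools stays open: of 73 transcripts of high L2C and low morula level, 63% in the Zfp622 knockout and 75.3% in the Ttf1 knockout lay above wild type in every library, and the former is under the limit of 67% set against mixing, by less than 2 standard errors of the share. Mixing alone would not explain every rise. Of members called higher, 11 of 41 in the Ttf1 knockout and 13 of 38 in the Zfp622 knockout need a larger share of L2C RNA than any of those transcripts showed. The median share needed was 2% and 1.72%, below the highest of those transcripts (7.94% and 6.31% of their L2C level).

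Lower ribosomal protein transcripts in Ttf1 knockout L2C embryos were not a matter of depth (-0.186 at equal depth). Lane stays open: the same lanes at morula gave a median of 0.0884 between the knockouts, but each knockout also moved the list against wild type there (0.25 and 0.14), so this does not isolate lane. Genes matched on exon length and level had a median of -0.0476, between the limits set, so a part of the shift may follow transcript length and level.

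Loss of the chromosome beyond the Cas9 cleavage site in some embryos is a hypothesis for the lower distal genes, with a median of -0.165 on chromosome 2 in the Ttf1 knockout. Proximal genes were also lower than other autosomes (-0.0693 against 0.0461), so loss of the whole chromosome stays open. On chromosome 15 the value of -0.0612 lay between the limits set for the test, and the question stays open.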
